A study of Mus musculus with 21 samples.

How the data were processed

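RNA of sorted mouse medulloblastoma cells had been hybridised to Affymetrix Mouse Genome 430 2.0 arrays, which carry 45101 probe sets. The deposited values are probe set intensities on a linear scale, between 0.025 and 55079. How the authors made them is not given in the sources used here. From the values, each array had been scaled so that the mean left after removing 2% of values at each end was 150.0, as Affymetrix's own software does, and the distributions had not been made equal between arrays. No step beyond this scaling is known.

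The plan fixed beforehand called for quantile normalization if the arrays had not been normalized to each other; the common trimmed mean was taken as such a normalization, and quantile normalization was run as an alternative. The intensities were used as deposited and put on a log scale as log2(signal + 32); the pseudocount of 32 damps the noise of dim probe sets and makes fold changes of dim genes smaller than on the raw scale. The 64 control probe sets were left out. Probe sets whose mean log2 value over the 21 arrays lay below the 40th percentile (a signal of about 15.5) were left out. Gene symbols came from the platform annotation: 34958 probe sets had 1 symbol, 932 had several and 9211 had none listed. Those with several or none were left out. Of these, 34754 matched a gene of the reference table (assembly GRCm38.p6, used for names only), and 0 symbols changed. The brightest probe set of each gene was kept, so that 12367 genes were tested; 6122 of them had more than 1 probe set past the filter, and these can disagree. The numbers of probe sets whose direction opposes the one used were recorded for each named gene.

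Samples were grouped by tumour model and CD15 fraction as the titles state. The descriptions of all 9 Math1-GFP samples call the tumours conventional, and the titles were followed. Conventional replicates are named by the number in their titles, with the unnumbered arrays called replicate 1. A model with 4 group means was fitted to all 21 arrays at once with limma 3.58.1 in R 4.3.3 (17 residual degrees of freedom), so that the groups share an estimate of the spread. There were 5 contrasts: the CD15 difference in each model, the interaction, the average over models, and Math1-GFP against conventional. P-values are two-sided from the moderated statistic of eBayes, with Benjamini-Hochberg adjustment over genes within a contrast and a threshold of 0.05. Errors are standard errors of the log2 fold change from that fit (SE) or standard deviations between arrays (SD).

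Before the data were examined, 22 gene lists (293 different genes, 226 measured) were fixed: Hedgehog pathway, granule neuron precursors, neuronal differentiation, S phase, G2 and M phase, apoptosis (promoting and restraining), p53 targets, neural stem cells, CD15 synthesis, immediate early genes, Wnt targets, hypoxia and glycolysis, and markers of astrocytes, oligodendrocytes, microglia, neutrophils, lymphocytes, endothelial, mural, erythroid and Purkinje or inhibitory cells. They were tested with camera at a preset inter-gene correlation of 0.01, adjusted over lists within a contrast. A list score is the mean log2 value of its measured genes on an array. With a correlation estimated per list, 2 of the 23 calls held, both in the average over models. Named genes followed a rule set at the same time: Fut4, Fut9, Ptch1 and Gli1; the 10 largest called changes in each direction (5 in the interaction and the model contrast), or the 5 of smallest p where fewer than 5 passed; and for each list the 4 members of smallest p if it passed, otherwise 1. Some genes of the rule are left out of the text for length.

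Titles give the numbers 2 to 6 in both conventional groups, and the fit described above did not use them. Same-numbered arrays deviated from their group means together: the correlation of deviations was 0.58 to 0.76 in the 5 pairs and at most 0.48 in other pairs, and each CD15 positive array was closest to its own number. The numbers were therefore taken to pair the samples, and the fit with the number as a block is given where it changes a call. That block left the Math1-GFP arrays unpaired, so their differences within a group stayed in the shared estimate of the spread. The unnumbered arrays correlated at 0.72. No number is shared by the Math1-GFP groups.

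Alternatives set beforehand were quantile normalization, pseudocounts of 1 and 128, no filter or a filter at the 60th percentile, every probe set or the mean of a gene's probe sets, fits of 2 groups alone, eBayes with trend and robust estimation, array weights, the replicate block, leaving out each array, an estimated correlation in camera, and fry. Added after seeing the data were a split of the conventional arrays by whole-array correlation (mean r = 0.958 within and 0.928 between the 2 sets), as a block and within each set; consecutive Math1-GFP numbers as a block; the data without Math1-GFP arrays 1 and 2, which stood apart; and, between models, the mean of each pair of arrays as 1 sample, with the unnumbered conventional arrays and consecutive Math1-GFP numbers as pairs and Math1-GFP array 4 left out. Other splits of the arrays were fitted at most 100 at a time with fixed seeds. One test set out as 100 random draws was run on all 90 possible selections instead. The ratio test used 200 genes per choice, a number not set beforehand, with 50 and 1000 tried beside it.

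The fit was tested on simulated data: values were drawn for the 12367 genes from their means and residual spreads, independently between arrays, with 200 genes changed. For the conventional comparison it called 81 of 100 genes changed by 1 on the log2 scale and 23 of 100 changed by 0.5, and for the Math1-GFP comparison 69 and 17. Among unchanged genes it called 4 and 3. Figures were drawn with matplotlib 3.10.9.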

Results

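Gene expression was measured on 21 microarrays of mouse cerebellar tumour cells sorted for the surface antigen CD15. The tumours were medulloblastomas of Patched mice. Patched (Ptch1) is the receptor that restrains Hedgehog signalling, and its loss leads to medulloblastoma in the granule neuron lineage of the cerebellum. CD15, also called Lewis X or SSEA-1, is a carbohydrate on the surface of several progenitor cell types and of neutrophils. The arrays fell into 4 groups: CD15 positive (n = 6) and CD15 negative (n = 6) cells of tumours named conventional, and CD15 positive (n = 4) and CD15 negative (n = 5) cells of tumours named Math1-GFP. Math1 (Atoh1) is a transcription factor of granule neuron precursors, and GFP a fluorescent reporter. The labels do not say that the samples of a group came from separate animals, so p-values measure the spread between these samples, which may in part be technical. Values are log2(signal + 32). The number of arrays limits the precision, since an array has no read depth. The median signal was 24.9 ± 1.94 (SD) in conventional CD15 positive, 26.3 ± 3.45 in conventional CD15 negative, 28.5 ± 2.99 in Math1-GFP CD15 positive and 28.4 ± 2.03 in Math1-GFP CD15 negative arrays. After filtering, 12367 genes were tested.

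The first comparison asked how CD15 positive cells of conventional tumours differ from CD15 negative cells of the same kind of tumour; CD15 had been proposed as a mark of the cells that propagate these tumours. Genes of mitosis rose in the CD15 positive cells and genes of neuronal differentiation fell. In the limma fit 1006 genes passed an adjusted p of 0.05, 377 higher and 629 lower in CD15 positive cells. Without CD15 negative array 5 the count was 606. Decreases were larger than increases: 120 called genes were at least 2-fold lower and 8 at least 2-fold higher. At an unadjusted p under 0.05 there were 2746 genes, against 618 by chance.

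Of the 21 measured genes of the G2 and M phase list, 19 rose over all genes tested and all 21 rose when adjusted over the list alone. The median log2 fold change was 0.82 (camera adjusted p = 4.2e-25, adjusted p = 0.067 with an estimated correlation). The list score was higher in the CD15 positive array of each of the 6 same-numbered pairs (the unnumbered arrays taken as a pair), by 0.65 to 1.20. Ube2c, a ubiquitin-conjugating enzyme that works with the anaphase-promoting complex, had a log2 fold change of 1.16 ± 0.18 (SE, adjusted p = 7.5e-04). Cyclin B2 (Ccnb2) changed by 1.04 ± 0.17 (adjusted p = 0.0010), the mitotic kinase Plk1 by 1.01 ± 0.17 (adjusted p = 9.4e-04) and Birc5, a subunit of the chromosomal passenger complex, by 1.00 ± 0.10 (adjusted p = 1.1e-05). The other large increases outside these 4 were Phgdh, the first enzyme of serine synthesis (1.06 ± 0.24), the phosphatase Cdc25c (1.04 ± 0.18), Cdca3 (1.03 ± 0.19), Sapcd2 (1.02 ± 0.17), the kinase Aurkb (1.01 ± 0.20) and the nuclear import factor Kpna2 (0.97 ± 0.16). Phgdh did not pass when a gene's probe sets were averaged (adjusted p = 0.12).

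Of 23 genes of DNA replication and S phase, 9 rose over all genes and 16 adjusted over the list alone; the median log2 fold change was 0.45 (camera adjusted p = 2.0e-12, adjusted p = 0.067 with an estimated correlation). Ribonucleotide reductase subunit Rrm1 changed by 0.51 ± 0.11 (SE, adjusted p = 0.0071) and the replication factor Gins1 by 0.54 ± 0.12 (adjusted p = 0.0084). The helicase subunits Mcm7 (0.42 ± 0.09, adjusted p = 0.0078) and Mcm5 (0.50 ± 0.11, adjusted p = 0.0087) passed here but not after quantile normalization (adjusted p = 0.23 and 0.068).

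Neuronal genes moved the other way. Of 18 measured members of the neuronal differentiation list, 14 fell over all genes and 16 adjusted over the list alone, with a median log2 fold change of -0.92 (camera adjusted p = 2.3e-13, adjusted p = 0.067 with an estimated correlation). The list score was lower in the CD15 positive array of all 6 pairs. The microtubule-associated protein tau (Mapt) had a log2 fold change of -1.55 ± 0.16 (SE, adjusted p = 8.6e-06), doublecortin (Dcx) of -1.22 ± 0.19 (adjusted p = 6.7e-04), and the synaptic proteins Snap25 and Syp of -0.83 ± 0.15 and -0.90 ± 0.17 (adjusted p = 0.0021 and 0.0027). The 10 largest decreases were led by the adhesion molecule L1cam (-2.22 ± 0.29, adjusted p = 1.4e-04). Dpysl3 (-1.97 ± 0.27), Stmn4 (-1.96 ± 0.28), Ndrg4 (-1.93 ± 0.25), Pdzrn3 (-1.91 ± 0.42), the neuronal kinesin Kif5a (-1.81 ± 0.25), the secretory granule protein Chgb (-1.77 ± 0.21), the axonal adhesion molecule Cntn2 (-1.72 ± 0.44), the tubulin-binding protein Stmn2 (-1.67 ± 0.40) and Sez6l2 (-1.66 ± 0.22) followed. Cntn2 did not pass without CD15 negative array 5 (adjusted p = 0.053), which held the highest neuronal score of its group (10.23).

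**Figure D1:**
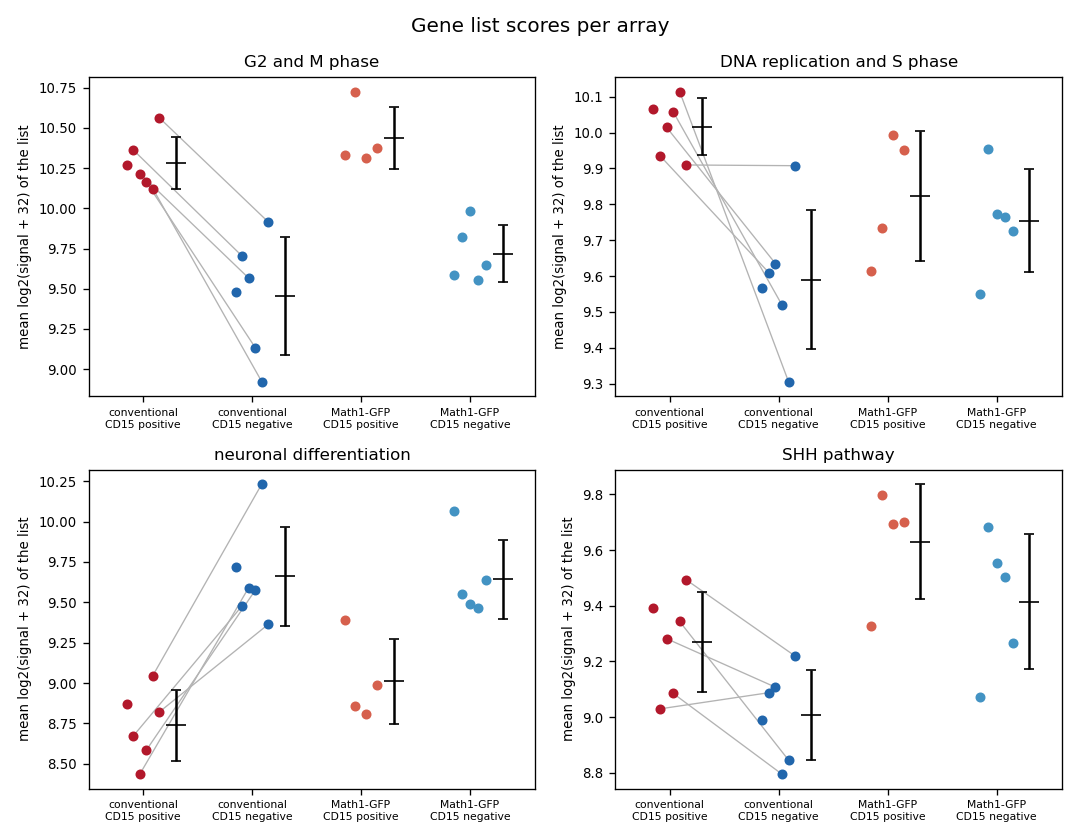
Mean log2(signal + 32) of 4 gene lists on each of the 21 arrays (points), with the mean and SD of each group (black bars); grey lines join conventional arrays with the same number in their titles, 2 to 6. The G2 and M phase scores of the 6 conventional CD15 positive arrays lie between 10.12 and 10.56, above the highest conventional CD15 negative array at 9.91.

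Hedgehog pathway genes were higher as a list in the CD15 positive cells of conventional tumours. The median log2 fold change of 14 measured members was 0.31 (camera adjusted p = 0.021, adjusted p = 0.42 with an estimated correlation), and 3 rose, also when adjusted over the list alone. Gli1, a transcription factor and target of the pathway, changed by 0.70 ± 0.21 (SE, adjusted p = 0.038), cyclin D1 (Ccnd1) by 0.46 ± 0.12 (adjusted p = 0.021) and the co-receptor Gas1 by 0.60 ± 0.18 (adjusted p = 0.0498). Among the numbered arrays alone Gli1 (adjusted p = 0.098, or 0.060 with the number as a block) and Gas1 (adjusted p = 0.079, or 0.064) did not pass. That block left the Math1-GFP arrays unpaired. With consecutive Math1-GFP numbers in the block as well, a pairing the labels do not state, Gli1 and Gas1 passed. Under quantile normalization neither the list (adjusted p = 0.070), Ccnd1 (adjusted p = 0.16) nor Gas1 (adjusted p = 0.071) passed. The list was also lost without CD15 positive array 6 (adjusted p = 0.092) or CD15 negative array 4. Gli2 was at 0.45 ± 0.20 (adjusted p = 0.19) and Ptch1 at 0.46 ± 0.39 (adjusted p = 0.55).

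Of 12 genes of the granule neuron precursor list, 3 fell, also when adjusted over the list alone. They were the transcription factors Nhlh1 (-1.52 ± 0.25, SE, adjusted p = 8.7e-04), Nhlh2 (-0.97 ± 0.29, adjusted p = 0.041) and Eomes (-0.81 ± 0.24, adjusted p = 0.040), of which Nhlh2 and Eomes were chosen after their values were seen. The list did not pass (median -0.27, camera adjusted p = 0.055), but did with the replicate number as a block (adjusted p = 0.035, adjusted p = 0.39 with an estimated correlation) and under quantile normalization (adjusted p = 0.0055, adjusted p = 0.18 with an estimated correlation). Fut9, a fucosyltransferase that makes the CD15 epitope in brain, was not higher in CD15 positive cells. Its log2 fold change was -0.44 ± 0.20 (SE, adjusted p = 0.19), and it was lower in the CD15 positive array of all 6 pairs. The other such enzyme, Fut4, lay below the filter on dim probe sets, and the list of 7 measured genes of CD15 synthesis had a median of -0.12 (camera adjusted p = 0.92).

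Markers of other cell types varied between arrays. The microglia and macrophage list was higher in CD15 positive cells of conventional tumours (median 0.72 over 14 genes, camera adjusted p = 0.021, adjusted p = 0.93 with an estimated correlation), with no member passing alone. C1qa was at 1.37 ± 0.65 (SE, adjusted p = 0.22), C1qb at 1.22 ± 0.61 (adjusted p = 0.25), C1qc at 1.17 ± 0.61 (adjusted p = 0.27) and Cd68 at 0.88 ± 0.49 (adjusted p = 0.30). Its score was 7.85 ± 1.37 (SD, n = 6 arrays) in CD15 positive and 7.17 ± 1.05 (SD, n = 6 arrays) in CD15 negative cells, and the call was lost when any of 6 arrays was left out (adjusted p up to 0.19, without CD15 positive array 4). The mural cell and fibroblast list leaned the other way without passing (median -0.59 over 9 genes, camera adjusted p = 0.090), and passed in the numbered arrays alone, without the replicate block (adjusted p = 0.046) and with it (adjusted p = 0.0010, adjusted p = 0.45 with an estimated correlation). Astrocyte (median 0.18), neural stem cell (0.33), oligodendrocyte lineage (0.13), neutrophil (-0.30) and endothelial (0.02) lists did not pass, with camera adjusted p between 0.18 and 0.97. The endothelial test leaned down although the median was positive. The astrocyte score was higher in the CD15 positive array of all 6 pairs, by 0.13 to 0.30, and the stem cell score in 5 of 6. With the number as a block these lists did not pass either (adjusted p = 0.48 and 0.094). Msi1, an RNA-binding protein of neural progenitors, was the only stem cell gene called (-0.44 ± 0.13, adjusted p = 0.041). It did not pass with every probe set (adjusted p = 0.055), with averaged probe sets (-0.29, adjusted p = 0.16), in the conventional groups alone (adjusted p = 0.10) or when any of 9 arrays was left out (adjusted p up to 0.11, without CD15 positive array 4). Lists of apoptosis (promoting, median -0.03; restraining, -0.03), p53 targets (-0.0039), immediate early genes (-0.08), Wnt targets (0.16) and hypoxia (0.25) did not pass either, with camera adjusted p between 0.53 and 0.97. Single genes nearest to the threshold in lists that did not pass included Cycs (0.38 ± 0.12, adjusted p = 0.055), Bbc3 (-0.51 ± 0.18, adjusted p = 0.088) and Slc1a2 (-0.73 ± 0.24, adjusted p = 0.068). Of the remaining lists, erythroid cells had 0, lymphocytes 1 and Purkinje cells and interneurons 2 measured genes, too few to describe.

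Whole-array correlation split the conventional arrays into numbers 2 to 5 and the unnumbered arrays with number 6. Within numbers 2 to 5 the comparison called 895 genes; within the other 4 arrays it called 0 with limma and 967 at an unadjusted p under 0.05. The G2 and M phase list had medians of 0.93 and 0.72 in the 2 sets, the S phase list 0.56 and 0.27, and the neuronal list -1.08 and -0.62, all past the camera test. With an estimated correlation none passed in either set (adjusted p = 0.088 for each list in the first, and 0.19, 0.50 and 0.19 in the second). The microglia list did not pass in the smaller set (median 0.43, adjusted p = 0.083).

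The same comparison was made in Math1-GFP tumours. Mitotic genes were again higher and neuronal genes lower as lists in camera, though not with an estimated correlation (adjusted p = 0.065 for both). Over all genes 1 of 21 mitotic and 0 of 18 neuronal genes passed. The fit called 5 genes, 2 higher and 3 lower, and 1073 at an unadjusted p under 0.05 against 618 by chance. With consecutive title numbers as a block, a pairing the labels do not state and that was chosen after seeing the data, 926 genes were called. Birc5 (0.74 ± 0.12, SE, adjusted p = 0.030) and the defensin Defa3 (0.80 ± 0.14, adjusted p = 0.043) rose. The phosphatase Dusp8 (-1.08 ± 0.18, adjusted p = 0.030), the neuronal membrane protein Plppr3 (-1.21 ± 0.21, adjusted p = 0.037) and Rmc1 (-0.60 ± 0.11, adjusted p = 0.037) fell. With every probe set none of the 5 passed (adjusted p = 0.071 for each). Defa3, Plppr3 and Rmc1 did not pass under quantile normalization (adjusted p = 0.064, 0.064 and 0.062). Defa3 and Plppr3 did not pass with the lower pseudocount (adjusted p = 0.13 and 0.087), nor did Defa3 and Rmc1 in the Math1-GFP groups alone (adjusted p = 0.056 and 0.081). Next in order, without passing, were Plk1 (0.93 ± 0.19, adjusted p = 0.078), Dlgap5 (0.69 ± 0.14, adjusted p = 0.078), Cdc25b (0.88 ± 0.18, adjusted p = 0.078), Mmp24 (-0.82 ± 0.15, adjusted p = 0.055) and Syt11 (-0.71 ± 0.13, adjusted p = 0.055).

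Of the G2 and M phase list in Math1-GFP tumours, 1 of 21 genes rose over all genes and all 21 adjusted over the list alone (median 0.74, camera adjusted p = 3.5e-30, adjusted p = 0.065 with an estimated correlation). Ube2c was at 0.96 ± 0.21 (SE, adjusted p = 0.096) and Ccnb2 at 0.89 ± 0.20 (adjusted p = 0.096). None of 18 neuronal genes passed over all genes and 8 fell adjusted over the list alone (median -0.59, camera adjusted p = 8.8e-12, adjusted p = 0.065 with an estimated correlation). Mapt was at -0.94 ± 0.18 (adjusted p = 0.061) and Cntn2 at -1.81 ± 0.51 (adjusted p = 0.17). The granule neuron precursor list was lower (median -0.25, camera adjusted p = 0.0054, adjusted p = 0.14 with an estimated correlation), and was lost without CD15 positive array 7 (adjusted p = 0.066). In it Nhlh1 was at -0.93 ± 0.29 (adjusted p = 0.21) and Meis1 at -0.52 ± 0.19 (adjusted p = 0.34). The S phase list did not pass (median 0.10 over 23 genes, camera adjusted p = 0.18), nor did the Hedgehog list (median 0.23, camera adjusted p = 0.051), in which Gas1 was at 0.85 ± 0.21 (adjusted p = 0.13). In pairs of consecutive numbers, which the labels do not state, the Hedgehog score was higher in the CD15 positive array of 4 of 4, by 0.19 to 0.43. The S phase score was higher in 3 of 4. Fut9 was at -0.48 ± 0.23 (adjusted p = 0.58), Gli1 at 0.47 (adjusted p = 0.61) and Ptch1 at 0.26 (adjusted p = 0.94). In the same pairs Fut9 was lower, and Gli1 and Ptch1 higher, in the CD15 positive array of 4 of 4.

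The neural stem cell and astrocyte lists were higher in CD15 positive cells of Math1-GFP tumours, while the oligodendrocyte lineage (median 0.31, camera adjusted p = 0.14) and microglia lists (median 0.46, camera adjusted p = 0.15) did not pass. In the pairs of consecutive numbers the oligodendrocyte score was higher in the CD15 positive array of 4 of 4, by 0.25 to 0.73, and the microglia score in 3 of 4. The neural stem cell and radial glia list had a median of 0.51 (12 genes, camera adjusted p = 8.2e-04, adjusted p = 0.098 with an estimated correlation). Its members nearest to the threshold were the transcription factor Sox2 (0.90 ± 0.33, SE, adjusted p = 0.36), the radial glial lipid-binding protein Fabp7 (2.09 ± 0.80, adjusted p = 0.38) and Prom1 (0.84 ± 0.34, adjusted p = 0.42). The astrocyte list had a median of 0.95 (11 genes, camera adjusted p = 0.0025, adjusted p = 0.13 with an estimated correlation), with the water channel Aqp4 at 1.41 ± 0.49 (adjusted p = 0.32) and Slc1a3 at 1.11 ± 0.47 (adjusted p = 0.46). CD15 positive array 1 held the highest astrocyte score, 9.01 against 7.64 for the next array of its group, and also the highest microglia score, 7.41 against 6.17. Without that array the astrocyte list did not pass (adjusted p = 0.16). Without Math1-GFP arrays 1 and 2 it did not pass either (adjusted p = 0.21), and 0 single genes did (852 at an unadjusted p under 0.05). Leaving out 1 array gave 0 to 13 genes: 0 without CD15 positive array 5, 7 or 9 or CD15 negative array 2, 4, 8 or 10, 7 without CD15 negative array 6, and 13 without CD15 positive array 1.

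**Figure D2:**
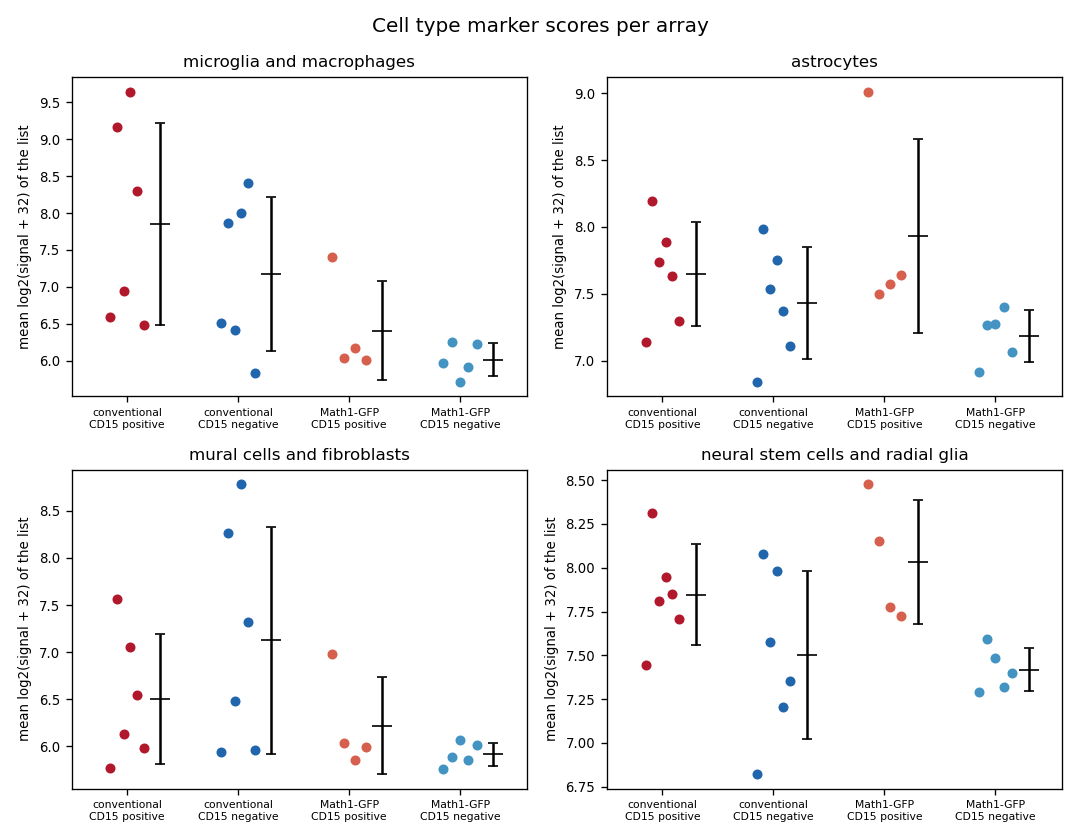
Mean log2(signal + 32) of 4 lists of cell type markers on each of the 21 arrays (points), with the mean and SD of each group (black bars). Math1-GFP CD15 positive array 1 lies at 9.01 in the astrocyte panel, and conventional CD15 positive arrays 2 and 4 lie at 9.16 and 9.65 in the microglia panel.

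The CD15 difference itself was compared between the 2 models. Across the 12367 genes the log2 fold changes of both models had Pearson r = 0.66 and Spearman rho = 0.61; genes are not independent replicates, and the 2 comparisons share no arrays. Of the 1006 genes called in conventional tumours, 979 (97.3%) had the same sign in Math1-GFP tumours. Both comparisons called 1 gene as higher and 3 as lower, against 0.061 and 0.15 for independent lists. The interaction called 0 genes in limma, with 279 at an unadjusted p under 0.05 where chance gives 618. With the conventional numbers as a block these counts were 0 and 662. With consecutive Math1-GFP numbers in the block as well they were 1 and 1263. The gene was Sorl1 (1.00 ± 0.12, SE, adjusted p = 0.043), named after its value was seen. In the interaction without a block, the smallest p-values in limma belonged to Vps13d (0.86 ± 0.23, SE), Srgap3 (1.12 ± 0.32) and Apc2 (0.76 ± 0.22) among genes with a more positive difference in Math1-GFP tumours. Among the others they belonged to Trmt44 (-0.76 ± 0.23), Ctbp2 (-0.43 ± 0.15) and Cenpw (-0.54 ± 0.19). All of these had an adjusted p of 1.00.

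As lists, 4 differed between the models in camera and 0 with an estimated correlation. The S phase list had a less positive CD15 difference in Math1-GFP tumours (median -0.33 over 23 genes, all 23 negative, adjusted p = 3.4e-14, adjusted p = 0.11 with an estimated correlation). Its members with the smallest p were Mcm5 (-0.50 ± 0.17, SE), Ccne2 (-0.61 ± 0.25), Cdc6 (-0.62 ± 0.26) and Cdt1 (-0.52 ± 0.23), none past the threshold. By pair, the CD15 difference in the S phase score was 0.0020 to 0.81 in conventional tumours. In pairs of consecutive Math1-GFP numbers it was -0.039 to 0.23, so the ranges overlap. The G2 and M phase list differed less (median -0.13, adjusted p = 0.042, adjusted p = 0.86 with an estimated correlation) and did not pass under quantile normalization (adjusted p = 0.79) or without Math1-GFP arrays 1 and 2 (adjusted p = 0.070). Leaving out 1 array ended it for 9 of the 21 arrays, with adjusted p up to 0.69, without conventional CD15 negative array 5. The neuronal list had a less negative difference (median 0.23, adjusted p = 0.0038, adjusted p = 0.63 with an estimated correlation). It did not pass without Math1-GFP CD15 positive array 1 (adjusted p = 0.19) or conventional CD15 negative array 5, nor against the unnumbered conventional arrays and number 6 (adjusted p = 0.82). The mural cell list differed by 0.92 (adjusted p = 3.6e-04, adjusted p = 0.63 with an estimated correlation), led by Pdgfrb (1.06 ± 0.48) and Rgs5 (1.40 ± 0.65), and did not pass without Math1-GFP CD15 positive array 1 (adjusted p = 0.0504). With the conventional numbers as a block, the astrocyte (adjusted p = 0.038), neutrophil (adjusted p = 0.035), neural stem cell (adjusted p = 0.044) and microglia (adjusted p = 0.0023) lists passed as well, and none of these 4 did with an estimated correlation (adjusted p = 0.56, 0.56, 0.46 and 0.65).

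**Figure D3:**
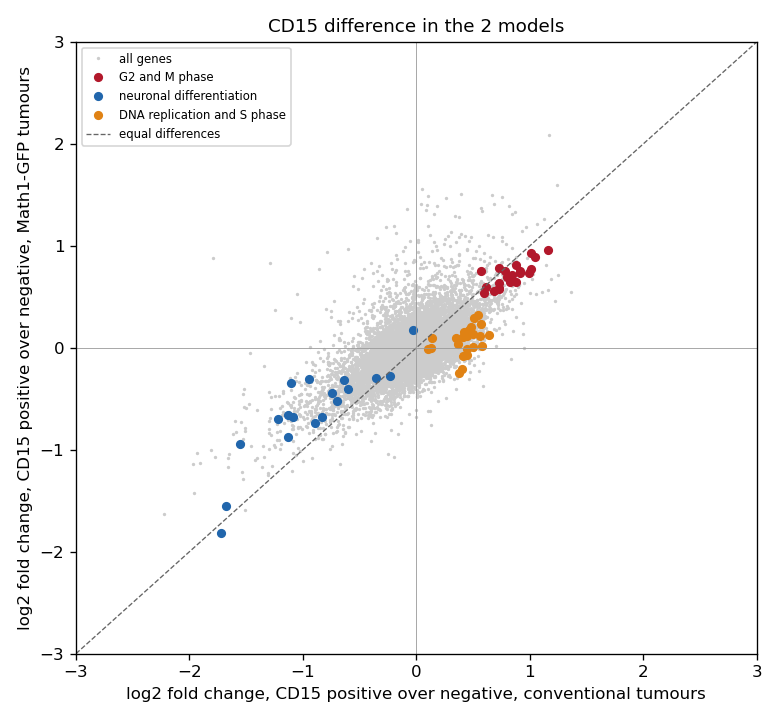
Log2 fold change of CD15 positive over CD15 negative cells in conventional (horizontal axis) and Math1-GFP tumours (vertical axis) for the 12367 genes tested (grey), with 3 gene lists in colour and the line of equal differences dashed. The 23 S phase genes all lie below that line, and their median is 0.45 in conventional and 0.10 in Math1-GFP tumours.

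Averaged over both models, with model held fixed, 1204 genes passed, 466 higher and 738 lower in CD15 positive cells; 858 of them were also called in conventional tumours and 346 were not. All 21 G2 and M phase genes rose (median 0.76, camera adjusted p = 1.6e-28) and 14 of 18 neuronal genes fell (median -0.74, camera adjusted p = 5.3e-14). Adjusted over the list alone, 21 and 16 passed. These 2 lists also passed with an estimated correlation (adjusted p = 0.043 for both), the only ones of the 8 called to do so. Birc5 (0.87 ± 0.08, SE, adjusted p = 2.0e-06), Plk1 (0.97 ± 0.13, adjusted p = 9.9e-05) and Ube2c (1.06 ± 0.14, adjusted p = 1.2e-04) rose, and L1cam (-1.93 ± 0.22, adjusted p = 2.4e-05), Mapt (-1.25 ± 0.12, adjusted p = 3.5e-06) and Stmn2 (-1.61 ± 0.31, adjusted p = 0.0018) fell.

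Of the genes named by the rule, 9 passed in the average over models that had not passed in either model. The membrane glycoprotein Pdpn (1.10 ± 0.32, SE, adjusted p = 0.033), the transcription factors Olig1 (1.08 ± 0.29, adjusted p = 0.019), Etv5 (1.08 ± 0.32, adjusted p = 0.037) and Sox2 (0.77 ± 0.22, adjusted p = 0.027), the water channel Aqp4 (1.05 ± 0.32, adjusted p = 0.044), the neuronal calcium sensor Hpca (0.93 ± 0.26, adjusted p = 0.029) and the stem cell surface protein Prom1 (0.79 ± 0.22, adjusted p = 0.027) were higher. The transcription factor Meis1 (-0.42 ± 0.12, adjusted p = 0.035) and the apoptosis gene Bbc3 (-0.47 ± 0.14, adjusted p = 0.034) were lower. By list, 2 of 12 stem cell, 1 of 11 astrocyte and 1 of 8 oligodendrocyte genes rose. Without Math1-GFP arrays 1 and 2, Pdpn (0.90, adjusted p = 0.070), Olig1 (0.96, adjusted p = 0.053), Etv5 (1.16, adjusted p = 0.054), Sox2 (0.60, adjusted p = 0.10), Hpca (0.95, adjusted p = 0.056), Prom1 (0.80, adjusted p = 0.056), Meis1 (-0.44, adjusted p = 0.055) and Bbc3 (-0.43, adjusted p = 0.091) did not pass. Aqp4 was then at 0.65 (adjusted p = 0.048). Aqp4 did not pass with the higher pseudocount (0.54, adjusted p = 0.10), averaged probe sets (0.64, adjusted p = 0.089), every probe set (adjusted p = 0.051), no filter on dim probe sets (adjusted p = 0.061), the numbered conventional arrays alone (adjusted p = 0.066, or 0.062 with the number as a block) or when any of 14 arrays was left out (adjusted p up to 0.073, without conventional CD15 positive array 2). With consecutive Math1-GFP numbers in the block as well, a pairing the labels do not state, Aqp4 passed. Of the other 8 genes, Olig1 alone passed whichever array was left out. The rest each lost the call at least once, with adjusted p up to 0.086 (Meis1 without Math1-GFP CD15 positive array 9). Hpca (adjusted p = 0.065) and Bbc3 (adjusted p = 0.063) did not pass under quantile normalization, nor did Meis1 with averaged probe sets (-0.26, adjusted p = 0.31). Etv5 did not pass with the lower pseudocount (adjusted p = 0.065) or no filter on dim probe sets (adjusted p = 0.052). With array weights Etv5 (adjusted p = 0.059) and Sox2 (adjusted p = 0.053) did not pass. The other called lists, with their adjusted p in camera and with an estimated correlation, were the Hedgehog pathway (0.014 and 0.32), granule neuron precursors (0.012 and 0.21), S phase (3.8e-07 and 0.21), neural stem cells (0.012 and 0.21), astrocytes (0.048 and 0.35) and microglia (0.020 and 0.89). The astrocyte and microglia lists did not pass without Math1-GFP arrays 1 and 2 (adjusted p = 0.31 and 0.18). Leaving out 1 array ended the astrocyte call for 13 of the 21 arrays and the microglia call for 5, with camera adjusted p up to 0.24 and 0.20. The Hedgehog and astrocyte lists did not pass under quantile normalization (adjusted p = 0.054 and 0.070).

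The last comparison described the 2 sets of tumours. On average microglial genes were lower in Math1-GFP than in conventional samples, but only conventional arrays 2, 4 and 5 had list scores above the Math1-GFP range. The fit called 4845 genes, 2309 higher and 2536 lower in Math1-GFP samples (47.7% higher). It counts every array as a sample, although arrays of a pair deviated together, so its p-values are too small if a pair is 1 tumour. With the mean of each pair as 1 sample (6 conventional, 4 Math1-GFP with consecutive numbers as pairs), a fit chosen after seeing the data, 2466 genes were called, 1111 higher and 1355 lower. Quantile normalization called 4851, of which 37.0% were higher. The majority turned with a gene's probe sets averaged (5195 called, 58.2% higher) and with every probe set (11418 called, 63.6% higher). All conventional titles carry one ending and all Math1-GFP titles another, so that tumour model and a batch of labelling, if the ending marks one, cannot be told apart. The ratio of 3' to 5' Gapdh probe sets, a sign of RNA or labelling quality, was 0.85 ± 0.07 (SD, n = 6) and 0.87 ± 0.05 (SD, n = 6) in the conventional and 0.74 ± 0.01 (SD, n = 4) and 0.72 ± 0.03 (SD, n = 5) in the Math1-GFP CD15 positive and negative groups.

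Of 14 microglia and macrophage genes, 13 were called lower in Math1-GFP samples, also when adjusted over the list alone (median -1.21, camera adjusted p = 0.0055, adjusted p = 0.73 with an estimated correlation), among them the signalling adaptor Tyrobp (-1.92 ± 0.49, SE, adjusted p = 0.0044), complement C1qa (-1.95 ± 0.50, adjusted p = 0.0045) and C1qb (-1.64 ± 0.47, adjusted p = 0.0093), and the receptor Csf1r (-1.79 ± 0.52, adjusted p = 0.0094). With pair means 1 of the 14 passed, the list median was -1.24 (camera adjusted p = 0.0051, adjusted p = 0.75 with an estimated correlation), C1qa passed (adjusted p = 0.047) and Tyrobp, C1qb and Csf1r did not (adjusted p = 0.053, 0.070 and 0.077). The list score was 7.87 to 9.65 in both fractions of conventional arrays 2, 4 and 5. It was 5.83 to 6.95 in the other 6 conventional arrays and 5.72 to 7.41 in the Math1-GFP arrays. Against the unnumbered conventional arrays and number 6 alone the list did not pass (median -0.088, adjusted p = 0.55), nor did Tyrobp, C1qa, C1qb or Csf1r (adjusted p = 0.13, 0.25, 0.40 and 0.96). That fit called 2621 genes, and 5682 were called against numbers 2 to 5 alone. With pair means the counts were 0 in limma (2799 at an unadjusted p under 0.05) and 3597. No other list passed. Under quantile normalization the Hedgehog (median 0.37, adjusted p = 0.0038), granule neuron precursor (median 0.25, adjusted p = 0.034) and G2 and M phase lists (median 0.28, adjusted p = 0.0038) passed as well, all higher in Math1-GFP samples, though not with an estimated correlation (adjusted p = 0.70 for each). The largest increases were the ubiquitin ligase Mid1 (3.51 ± 0.51, adjusted p = 2.1e-05), Sowaha (2.95 ± 0.55, adjusted p = 2.9e-04), Mab21l2 (2.53 ± 0.65, adjusted p = 0.0044), the receptor Epha8 (2.48 ± 0.53, adjusted p = 0.0011) and cathepsin E (Ctse, 2.32 ± 0.25, adjusted p = 8.3e-07). The largest decreases were Edaradd (-2.93 ± 0.66, adjusted p = 0.0015), Sbspon (-2.43 ± 0.44, adjusted p = 2.2e-04), keratin Krt12 (-2.42 ± 0.90, adjusted p = 0.038) and lysozyme Lyz1 (-2.40 ± 0.63, adjusted p = 0.0051). With pair means Mab21l2 (adjusted p = 0.065), Krt12 (adjusted p = 0.21) and Lyz1 (adjusted p = 0.055) did not pass. The fifth decrease by the rule was the Y-linked Eif2s3y (-2.34 ± 0.73, adjusted p = 0.015, or 0.12 with pair means), whose size depends on the pseudocount, since its Math1-GFP values lay near the floor. Eif2s3y was high (9.30 to 9.75) in both fractions of conventional arrays 2, 4 and 5, at most 5.52 in the other 6 conventional arrays and at most 5.09 in all 9 Math1-GFP arrays. In conventional arrays 2, 4 and 5 Xist, the RNA of the inactive X chromosome, was low (5.10 to 6.18), the pattern of male cells. The titles do not give sex. The Eif2s3y decrease follows which samples carry a Y-linked transcript, so it cannot be read as a difference between tumour models. The same conventional arrays 2, 4 and 5 held the high microglia scores. Against the unnumbered arrays and number 6, Epha8 (0.42, adjusted p = 0.39), Edaradd (-0.87, adjusted p = 0.05002) and Lyz1 (-0.80, adjusted p = 0.36) did not pass. Sowaha (0.75), Mab21l2 (0.91) and Ctse (1.36) passed with smaller differences. Krt12 was higher in Math1-GFP samples (0.57) without passing.

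Single members of other lists also differed between the sets of tumours. The Hedgehog co-receptor Gas1 (1.01 ± 0.14, SE, adjusted p = 1.5e-05), the precursor transcription factor Pax6 (1.03 ± 0.26, adjusted p = 0.0042), the mitotic transcription factor Foxm1 (1.26 ± 0.15, adjusted p = 2.7e-06), Sox2 (0.96 ± 0.22, adjusted p = 0.0017) and the growth factor receptor Pdgfra (1.75 ± 0.29, adjusted p = 7.9e-05) were higher in Math1-GFP samples. The immediate early gene Btg2 (-1.42 ± 0.24, adjusted p = 9.4e-05), the glucose transporter Slc2a1 (-0.92 ± 0.16, adjusted p = 1.1e-04) and the apoptosis regulator Bag1 (-0.62 ± 0.07, adjusted p = 1.3e-06) were lower. Pax6 did not pass against the unnumbered conventional arrays and number 6 (adjusted p = 0.22) or with pair means (adjusted p = 0.056). The other 7 passed with pair means.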

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

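The splits of pair means, the look at which arrays other Math1-GFP splits group, and the tests of the 2 sets of conventional arrays, of consecutive Math1-GFP numbers and of the 3 explanations for the difference between models were chosen only after the results were seen. In each group the highest and the lowest array were compared with the rest by Dixon's test, for each list score, quality measure and named gene. It singled out 47 of 636 cases, against 31.8 by chance, since chance singles out about 1 in 20. Values are log2(signal + 32).

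Math1-GFP CD15 positive array 1 stood above the other 3 of its group in markers of several cell types. Its list scores were 9.01 for astrocytes, 7.41 for microglia, 7.52 for neutrophils and 6.98 for mural cells. It was also highest for the microglial genes C1qb (8.44), Csf1r (8.20) and Fcgr3 (7.32), the neutrophil gene S100a9 (7.91), the fibroblast and mural genes Col1a1 (5.69), Lum (6.28), Pdgfrb (6.04) and Tagln (7.15), Pdpn (9.10), and the neuronal genes Dcx (10.52) and L1cam (8.28). It was lowest for Gli1 (8.62) and Atl3 (7.86). In the same group array 5 had the highest G2 and M phase score (10.73), and array 9 was highest for Ccne2 (9.04) and Psmc3ip (8.97).

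Among Math1-GFP CD15 negative arrays, array 2 was highest for the neuronal list (10.07), Dusp8 (9.03), Pax6 (11.39) and S100a9 (7.14), and lowest for Boc (8.33), Pdgfra (9.78) and Slc1a2 (8.90). Array 10 was lowest for Etv5 (6.66) and Slc1a3 (6.33) and highest for Pdgfrb (5.46).

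Among conventional CD15 positive arrays, array 5 was highest for the neutrophil list (6.58), Lcn2 (8.41) and S100a9 (6.94). Array 4 was lowest for Defa3 (5.45), array 6 highest for Foxm1 (8.57), array 2 highest for Slc1a3 (9.11) and the unnumbered array highest for Mid1 (8.79). Among conventional CD15 negative arrays, array 5 was highest for Aqp4 (6.09), Csf3r (8.50), Dpysl3 (10.41), Fut9 (8.97), Lcn2 (7.06), Nhlh1 (11.54) and the 3' to 5' ratio of actin (1.84). Array 6 was highest for Cdc25c (8.80), and the unnumbered array was highest for Mid1 (8.30) and lowest for B4galt1 (6.54).

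The CD15 difference itself differed between models in camera for 4 lists, with a median interaction of 0.23 for neuronal differentiation, -0.33 for S phase, -0.13 for G2 and M phase and 0.92 for mural cells. None of the 4 passed with an estimated correlation, where the smallest adjusted p was 0.11.

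Other splits of the arrays were fitted to ask whether chance can be excluded for each count of genes. For CD15 in conventional tumours, 1 of 100 splits, the real one, called as many as the 1006 genes (highest other 688). Of the 32 splits that part every pair, 1 did, and no other called any gene (highest other 0). The average over models (1 of 100, real 1204, highest other 79) and the comparison of models (1 of 100, real 4845, highest other 1346) likewise stood alone. With the mean of each pair of arrays as 1 sample, the comparison of models called the most genes among the 100 splits drawn (real 2466, highest other 1974). Another split came near the real count and not every possible split was drawn. It is therefore not shown that no other split reaches the real count. For CD15 in Math1-GFP tumours 4 of 100 splits called at least the 5 real genes. The other 3 called 31, 17 and 12, which points to a structure of the samples: each kept consecutive numbers together, with arrays 1 and 2 in the group of 4. The 11 other splits that part all 4 pairs of consecutive numbers called 0 in limma, and these numbers as a block called 926 in the real split. For the interaction all 100 of 100 splits reached the real count of 0 (highest other 12); every split reaches a count of 0, so this says nothing about chance.

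Mitotic genes were higher and neuronal genes lower in CD15 positive cells of conventional tumours. The scaling of the arrays is argued against as the whole cause, since the median of the G2 and M phase list was 0.76 under quantile normalization. A difference between the 2 sets of conventional arrays could not give this pattern by itself, since each set holds as many CD15 positive as CD15 negative arrays. The G2 and M phase list was higher within each set, with the lower of the 2 medians at 0.72. Normal granule neurons left among the CD15 negative cells could contribute: the median of 6 measured markers of mature granule neurons, out of 11 listed, was -0.27 (interquartile range -0.37 to -0.22) against -0.92 for the neuronal list, which neither meets nor excludes what such cells would give, and 1 of the 6 is also in the neuronal list. Grin2c (5.49), Kcnd2 (5.52), Cbln3 (5.93) and Calb2 (6.27) were dim in the conventional CD15 negative cells, where the pseudocount makes a fall smaller. The brighter markers Camk4 and Cbln1 were at -0.78 and -0.30. A difference in the state of the tumour cells themselves stays open.

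Far fewer genes were called in Math1-GFP than in conventional tumours, 5 against 1006. The smaller number of arrays is argued against, since 0 of the 90 selections of 4 CD15 positive and 5 CD15 negative conventional arrays called as few (lowest 234, median 516, highest 1055). Whether a smaller CD15 difference contributes is not decided. With genes chosen in 3 conventional replicates and measured in the other 3, the median ratio of the Math1-GFP to the conventional difference was at most 0.79 over 20 choices. Choosing genes by their conventional difference alone favours a low ratio wherever the models change partly different genes. The reverse choice, in Math1-GFP arrays, was not made. Differences between tumours shared by consecutive numbers may contribute, since taking these numbers as a block called 926 genes, but the labels do not state that pairing. The block did not close the gap. In conventional tumours the same fit called 2898 genes, against 704 for the same arrays without the block. Both stay open.

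Math1-GFP and conventional samples differed in 4845 genes, or 2466 with the mean of each pair as 1 sample. Conventional arrays 2 to 5 as the cause stay open for the genes at large: 2621 genes were called against the other 4 conventional arrays, but with these as 2 pair means 0 were in limma (2799 at an unadjusted p under 0.05, chance 618). For the respiratory chain and ATP synthase, a family chosen after seeing the data, the fall was of like size against both sets, which does not decide the cause. Of its 82 genes, 69 fell against the other 4 arrays (median -0.70, camera adjusted p = 0.031 with an estimated correlation). Against arrays 2 to 5, 72 fell (median -0.69). These 2 fits count every array as a sample, although arrays of a pair deviated together. The 0 calls with pair means cover this family too, so conventional arrays 2 to 5 stay open as its cause. Fewer microglia also stay open for the genes at large, because of the 0 calls with pair means, although the microglia list had a median of -0.088 against the other 4 conventional arrays. The respiratory chain family fell against those 4 arrays as well, but that fit counts arrays of a pair as separate samples. Fewer microglia therefore stay open for this family too. A labelling batch cannot be told apart from the tumour model, because 0 Math1-GFP titles carry the ending of the conventional ones. The sex of the animals was not tested, and the Y-linked Eif2s3y was high only in conventional arrays 2, 4 and 5. The model itself stays among the open explanations, as untested.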

How the results depend on the processing

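The array sets, the pair means, the consecutive-number block and the data without Math1-GFP arrays 1 and 2 were chosen after seeing the data. Among single genes, reversals were checked for the named ones only. No alternative reversed a called named gene except Krt12 between models (0.57 against the unnumbered conventional arrays and 6). Named genes kept 1087 of 1140 calls and lists 251 of 297 under the other alternatives set beforehand, 1737 of 1890 and 338 of 378 when 1 array was left out, and 426 of 532 and 104 of 116 under those added. An estimated correlation ended 21 of 23 list calls, fry 11. The Math1-GFP count of 5 became 3 under quantile normalization, 3 with the lower and 17 with the higher pseudocount, 0 with every probe set (more tests), 8 with averaged probe sets, 9 with its own groups alone, 11 with trend and robust, 187 with array weights, 926 with the consecutive-number block and 0 without arrays 1 and 2. That block gave 2898 in conventional tumours, 1 in the interaction and 3673 averaged. The conventional replicate block gave 1235 (768 for the same arrays without it), 0 and 1755 (1130). Against the same arrays without it, it ended no call of a named gene or list. Every probe set gave 1817 averaged and 11418 between models, from more tests. The unnumbered arrays and 6 gave 0, 250 averaged and 2621 between models, with fewer arrays; 2 to 5 alone gave 1 in the interaction (Disp2, named after its value was seen). Agreement fell to r = 0.53 with the lower pseudocount. Leaving out 1 array gave 606 to 1047, 0 to 13, 0, 921 to 1289 and 4420 to 5100 in the 5 comparisons. Pair means gave 2466 between models, with fewer samples. Other causes were not tested. Dim genes are limited by signal over background.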

Other observations

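The gene families here, and the tests on consecutive Math1-GFP numbers, were chosen after seeing the data. Centromere proteins, which build the attachment site of chromosomes to the spindle, rose in CD15 positive cells of conventional tumours. Of 21 measured, 15 rose (median log2 fold change 0.57, camera adjusted p = 2.7e-17, and 8.0e-04 with an estimated correlation), and 16 under quantile normalization. Cenpe and Cenpf are also in the G2 and M phase list, and the family was picked after that list's result. It is therefore not separate support for the rise of mitotic genes. In Math1-GFP tumours 0 passed in limma, with a median of 0.34 (camera adjusted p = 2.9e-12, and 0.0048 with an estimated correlation). Semaphorins, secreted and membrane guidance proteins of growing axons, were lower in conventional CD15 positive cells, where 3 of 17 fell (median -0.29, camera adjusted p = 0.0013, and 0.027 with an estimated correlation, but 0.075 with it in arrays 2 to 5 alone and 0.13 in the other 4). In Math1-GFP tumours 0 of 17 passed in limma and the family did not (median -0.10, camera adjusted p = 0.22). The respective medians under quantile normalization were 0.61 for centromere proteins and -0.22 for semaphorins.

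Genes of the respiratory chain and ATP synthase were lower in Math1-GFP than in conventional samples. Of 82 measured, 74 fell and 1 rose (median -0.70, camera adjusted p = 2.5e-36, and 0.0035 with an estimated correlation), and 67 fell under quantile normalization (median -0.49). Against conventional arrays 2 to 5 alone 72 fell, against the other 4 conventional arrays 69, and with the mean of each pair of arrays as 1 sample 68. Proteasome subunits fell in 28 of 38 cases (median -0.42, camera adjusted p = 4.4e-13, and 0.089 with an estimated correlation), or 23 under quantile normalization and 22 with pair means. Ribosomal protein genes had a median of -0.59, with 37 of 48 lower, but -0.05 under quantile normalization (adjusted p = 0.53), so that their difference depends on the scaling. Tumour model and title ending cannot be told apart here either.

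A hypothesis is that consecutive numbers of the Math1-GFP titles, such as 1 and 2, are the 2 fractions of 1 tumour. Arrays with consecutive numbers deviated from their group means together, with correlations of 0.59 to 0.68 against at most 0.14 for other pairs. Of the 120 ways to assign CD15 negative to CD15 positive arrays, 1, the consecutive one, had as high a mean correlation (0.63, next best 0.51, exact one-sided permutation p = 0.0083). This is consistent with the hypothesis, but the labels do not state it. The same test on the conventional numbers gave 1 of 120 as well (0.64, next best 0.55).

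Both conventional arrays 6 and Math1-GFP arrays 9 and 10 showed little Xist, the RNA of the inactive X chromosome, and little of the Y-linked Eif2s3y. Xist was 5.54 and 5.83 in the conventional pair and 6.56 and 6.42 in Math1-GFP arrays 9 and 10, against 10.06 to 13.00 in arrays with high Xist. Eif2s3y was 5.04, 5.39, 5.02 and 5.01, against 9.30 to 9.75 in the arrays where it was high. A hypothesis is that 1 sex chromosome may be missing from these tumour cells. Then the mean of 4 X-linked genes that escape inactivation should lie below every high-Xist array of the same model, which held in 3 of the 4 arrays. Conventional arrays 6 (9.771 and 9.744) also lay above the 6 conventional arrays with high Eif2s3y (9.403 to 9.734, SD 0.12), where a single X in both would give like values, but by less than that spread. Math1-GFP array 9 (9.799) lay above the lowest high-Xist array (9.798) by far less than the spread of those arrays (SD 0.17). By the bound first set, this array would have counted against the hypothesis. The requirement that it do so by more than the spread was applied after the values were seen, and the test leaves the hypothesis undecided.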
